A study of Mus musculus with 4 samples.

How the data were processed

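The WT, JVF, MPN and AML libraries, 1 per group, were each made from sorted mouse progenitors with a Chromium 3′ kit. The deposited files hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger on mm10 and given as filtered barcodes. Per the file headers the matrices are format 2 from software version 3.1.0, and the processing notes name Cell Ranger and Seurat without versions. Whole numbers of 1 or more filled every matrix, and no normalization was applied to them. Of 31053 genes in the files, 31011 (99.9%) matched the annotation by identifier.

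Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. The share of barcodes over the mitochondrial limit was 65.9% in WT, 56.5% in JVF, 54.6% in MPN and 60.9% in AML. Scrublet (in scanpy 1.11.5) removed 22, 118, 77 and 32 doublets, with a fallback to the expected rate of 0.8% per 1000 barcodes where the automatic threshold marked under 0.5%. The kept cells held 44293412, 79821990, 41550491 and 55347338 UMIs, with medians of 3277, 3430, 2874 and 3128 genes per cell. All 4 libraries were clustered together without batch correction, on 2000 highly variable genes, 30 principal components and 20 neighbors, with Leiden at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9).

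Clusters were named from 13 marker lists. A marker counted where it was at least 2-fold above the other cells and had a UMI in at least 10% of the cluster's cells, 3 markers were needed, and the class had to lead among the 10 leading genes. A cluster with at least 90% of its cells, and at least 100 cells, from 1 library was set apart as specific to it. The markers were fixed before the data were examined, as were the comparisons, the 18 gene lists, the named genes and the alternatives, except where a choice is said to have been made later. The naming rule for clusters was set after the data were seen.

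Sums of UMIs over the kept cells of a library, or over its erythroid-like or HSC/MPP-like cells, were scaled to CPM and compared as JVF against WT, MPN against JVF, AML against MPN, and AML against WT. Each ratio has an exact conditional binomial interval at 95%. A gene is called higher or lower where the ratio is at least 1.5-fold in either direction and the interval leaves out 1, which is a rule of size and not a test. A library at 0 was set to a floor of 3 counts. A list's median covers members with at least 30 UMIs over the 2 libraries, and its percentile is among 10000 random lists of the same size matched on mean expression, a description of these libraries. No p-value was computed, since cells of 1 library are not replicates. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and, for scaling factors, R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, all with seed 1.

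The genes named follow a fixed rule. They are Trp53, Jak2, Bmp2, Kit and Ly6a in every comparison. For each of the 3 successive comparisons they are also the 8 highest and 8 lowest ratios among genes with at least 100 UMIs over the 2 libraries and at least 20 CPM in 1 of them, and the 5 highest and 5 lowest within each of the 2 classes where both libraries held at least 100 cells. Mitochondrial, Rpl and Rps genes, Xist, Y-linked genes, gene models and RIKEN clones were left out of these ranks. From each list up to 4 members with the largest absolute log2 ratio are named by the rule. Of these the text prints all 4 for p53 targets, JAK2/STAT5 targets and BMP/SMAD target genes (2 within a class) and 1 for each other list, a limit set after the results and their alternatives had been seen. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, which left out 86, 60, 58 and 77 shallower cells.

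Alternatives were TMM and median-of-ratios factors, each cell weighing the same, a looser cell filter (200 genes, 500 UMIs, 20% mitochondrial) and a stricter filter (1000 genes, 2000 UMIs, 5%). Further ones were doublets kept, thinned cells, class weights made the same in every library, hemoglobin genes left out of the total, and list members with at least 1 UMI in each library or at least 200 over both. The equal class weights leave out a cluster set apart as specific to 1 library. Clustering was repeated at resolutions 0.5 and 2.0, with 15 components, without cell cycle genes and in each library alone. The ratio procedure was tested on simulated data, drawn as Poisson counts at known folds on the depths of the MPN and JVF libraries. Of genes simulated at 2-fold, 98% were called, at 1.25-fold 4%, and of genes without a difference 0.577%. A simulated list at 2-fold reached percentile 100.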

Results

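Single-cell RNA sequencing (Chromium 3′) measured progenitor cells of C57BL/6 mice in a model that runs from a myeloproliferative neoplasm (MPN) to acute myeloid leukemia (AML). The 4 libraries were wild type (WT), Jak2 V617F (JVF), Jak2 V617F with Tp53 null at the MPN stage (MPN) and the same genotype at the AML stage (AML), with 1 library per group. The labels call the sorted cells LSK in the titles and lineage-negative, Kit-positive in the cell type field, and the gate used is not settled by the sources used here. The WT library held 9717 barcodes and 57118927 UMIs (molecules counted), the JVF library 12643 and 100532302, the MPN library 8668 and 52497814, and the AML library 11257 and 78695918. The cell filter kept 3139, 5141, 3817 and 4118 cells in that order, with medians of 12394, 13261, 8753 and 11458 UMIs per cell. Ratios compare sums of UMIs per library as CPM, counts scaled to the same library total, with exact conditional binomial intervals, and shares have exact Clopper-Pearson intervals, all at 95% and for counting error only. For a share of 0 the upper limit is 3 counts of the total. There are no replicates, so no difference was tested, and "higher" and "lower" describe these libraries. By Xist (1290.0 CPM) the JVF library came from female cells, and by Y-linked genes the other 3 came from male cells, so comparisons with JVF also differ by sex.

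The altered gene Trp53 (chromosome 11, 69580359 to 69591873, mm10) was read at 115 CPM in WT, 199 in JVF, 138 in MPN and 116 in AML. A 3′ tag does not check the deletion, whose exons are not given in the sources used here. Jak2 (chromosome 19, 29251828 to 29313080) was read at 15.1, 22.0, 28.8 and 18.0 CPM, and the V617F change is not visible in gene counts. Bmp2 (chromosome 2, 133552159 to 133562885), a ligand of the BMP/SMAD pathway, had 0, 3, 0 and 0 UMIs, so no ratio is given. After each cell was thinned to 2000 UMIs, no cell of any class in any library had a Bmp2 UMI. In erythroid-like cells that was 0 of 590 WT, 0 of 1085 JVF, 0 of 954 MPN and 0 of 832 AML cells, which allow shares of cells with a UMI of up to 0.508%, 0.276%, 0.314% and 0.361%. Kit, the stem cell factor receptor, was at 106, 100.1, 119 and 149 CPM, and Ly6a, which encodes Sca-1, at 10.4, 12.9, 10.04 and 9.25.

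Clustering all kept cells together gave 23 clusters, named from marker genes as progenitor classes. Stem and multipotent progenitor-like (HSC/MPP-like) cells were 15.005% of WT, 12.95% of JVF, 17.9% of MPN and 12.1% of AML cells. Megakaryocyte-like cells were 13.8% of WT, 9.47% of JVF, 9.35% of MPN and 5.34% of AML cells. Granulocyte progenitor-like cells were 14.3% of WT, 15.2% of JVF, 7.78% of MPN and 10.8% of AML cells, and monocyte/dendritic progenitor-like cells 8.60% of WT, 8.95% of JVF, 6.81% of MPN and 12.4% of AML cells. Lymphoid-primed progenitor-like cells were 1.88% of WT, 1.23% of JVF, 0.734% of MPN and 3.21% of AML cells, and basophil/mast-like cells 4.91% of WT, 5.21% of JVF, 5.06% of MPN and 3.42% of AML cells. Erythroid-like cells were 18.8% of WT, 21.1% of JVF, 24.99% of MPN and 20.2% of AML cells. No direction is drawn from the erythroid-like share, because its differences changed sign under alternatives. In JVF against WT the difference was 2.28 percentage points, but -5.82 with the stricter filter. With each library clustered alone, MPN against JVF went from 3.89 to -19.8 and AML against MPN from -4.77 to 22.4. Tcrg-C1, a T cell receptor gamma gene, is also a leading gene of erythroid-like clusters 2 and 10 and had 3 UMIs in WT and 2048 in JVF. Unnamed clusters held 22.7% of WT, 25.9% of JVF, 27.4% of MPN and 24.3% of AML cells.

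A cluster of 336 cells, 8.16% of the AML library (7.34 to 9.04%), had no cell from another library. Such clusters held 13.4% of AML cells with the looser cell filter and 20.96% at resolution 2.0, and none formed with the stricter filter. The absence there is no check of the 336 cells, whose median mitochondrial share of 7.11% lay above that filter's limit of 5%. The 0 of 3139 WT, 0 of 5141 JVF and 0 of 3817 MPN cells allow shares of up to 0.0956%, 0.0584% and 0.0786%. The leading genes of the 336-cell cluster were Hbb-bt, Cdkn2a, Gml2, Hba-a1, Cela1, Bex4, Bmp4, Tnni3, Cldn3 and Syngr1, and the cluster is treated as part of that library, not as a cell type. By its markers it scored highest as erythroid (13 markers counted), but the rule for clusters of 1 library set it apart. The erythroid-like share of AML cells leaves these cells out. The same class lay in different clusters in different libraries. HSC/MPP-like cells were mostly in cluster 8 in WT (376 cells) and in cluster 1 in JVF (427), MPN (543) and AML (409). Erythroid-like cells were most often in cluster 10 in WT (277), in cluster 2 in JVF (496) and MPN (509), and in cluster 4 in AML (339).

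**Figure D1:**
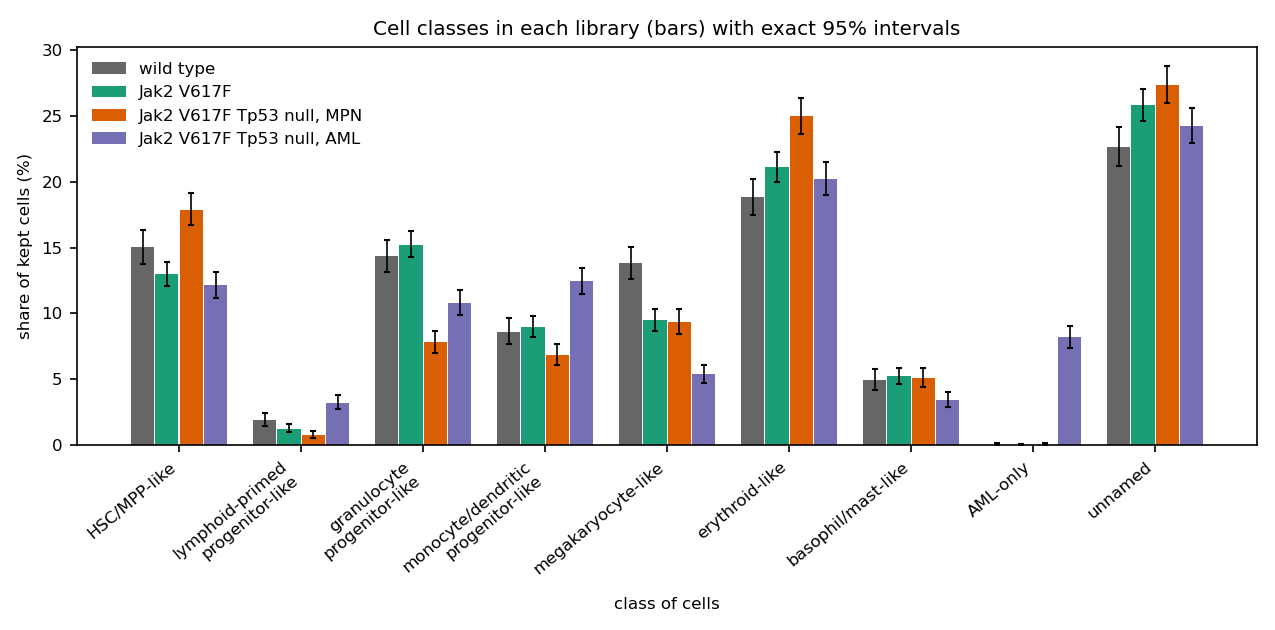
Share of kept cells (%, y axis) in each class (x axis) for the 4 libraries, with exact 95% binomial intervals as error bars. Megakaryocyte-like cells were 13.8% of WT and 5.34% of AML cells.

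JVF against WT asks what differs with the Jak2 mutation, in libraries that also differ by sex. Among the lists given here, the median ratios of interferon response, MHC class II, heme synthesis and G2/M phase genes and of erythroid and monocyte/dendritic markers lay above the central 95% of matched random lists, and those of glycolysis genes and granulocyte progenitor markers below it. JAK2/STAT5 targets and p53 targets had more members higher than lower. Megakaryocyte-like cells were less frequent, at a ratio of 0.687 (0.602 to 0.783). Each gene is followed by its ratio and interval, ratios printed alone have intervals that leave out 1, and a list's median log2 ratio is followed by its percentile among 10000 random lists matched on expression.

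Trp53 was higher in JVF (1.73, 1.68 to 1.79), also in HSC/MPP-like cells (1.88, 1.67 to 2.13). In erythroid-like cells it was higher by the rule (1.51, 1.44 to 1.59, log2 ratio 0.60), but under 1.5-fold with TMM and median-of-ratios factors (0.53 and 0.52). Ratios of Jak2 (1.46, 1.33 to 1.60), Kit (0.940, 0.906 to 0.974) and Ly6a (1.24, 1.11 to 1.38) in all kept cells stayed below 1.5. Within erythroid-like cells they were Jak2 (1.13, 0.968 to 1.32) and Kit (0.702), and within HSC/MPP-like cells Jak2 (1.73), Kit (1.27) and Ly6a (1.67). JAK2/STAT5 targets had 3 of 15 measured members higher and 0 lower, with a median of 0.20 (percentile 93.8). The sialomucin gene Podxl (37.6, 26.3 to 55.9) stood at 25.5 against 0.677 CPM, the feedback inhibitor gene Socs2 (2.47, 1.95 to 3.14) at 4.90 against 1.99 CPM and the cytokine gene Osm (2.39, 1.93 to 2.99) at 5.56 against 2.33 CPM. Another feedback inhibitor gene, Cish (1.28, 1.04 to 1.58), stayed below 1.5. Thinning each cell to 2000 UMIs gave log2 ratios of 4.15 for Podxl and 0.46 for Socs2, against 5.23 and 1.30. The median was 0.33 (percentile 98.4) in erythroid-like cells, with Podxl (341, 94.1 to 2814, 1792 against 2 UMIs) and Socs2 (11.1, 4.65 to 34.7, 146 against 5 UMIs) highest. It was 0.41 (percentile 98.7) in HSC/MPP-like cells, with Podxl (2.83, 1.31 to 6.81, 29 against 9 UMIs) and Socs2 (1.74, 1.17 to 2.61), and the stricter cell filter gave Socs2 a log2 ratio of -0.16 there.

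Of 29 measured p53 targets, 6 were higher in JVF and 0 lower, with a median of 0.17 (percentile 88.6). The RNA-binding protein gene Zmat3 (4.49, 3.47 to 5.90) stood at 6.59 against 1.47 CPM, Phlda3 (2.76, 2.21 to 3.48) at 5.93 against 2.14 CPM and the noncoding RNA gene Pvt1 (1.92, 1.69 to 2.19) at 13.7 against 7.11 CPM. The receptor gene Eda2r (3.79, 1.60 to 10.9, 41 against 6 UMIs) rests on few UMIs. Thinning left still fewer and gave a log2 ratio of -1.32, from which no direction is drawn. In erythroid-like cells 10 of 25 were higher and 0 lower (median 0.55, percentile 100), led by the cell cycle inhibitor gene Cdkn1a (5.46, 2.68 to 12.96, 115 against 8 UMIs) and Phlda3 (5.03, 3.40 to 7.73). In HSC/MPP-like cells 8 of 20 were higher (median 0.33, percentile 93.3), led by the apoptosome gene Apaf1 (2.23, 1.63 to 3.08) and Btg2 (2.19, 1.71 to 2.82).

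BMP/SMAD target genes went both ways in JVF (median 0.016, percentile 24.4, 10 measured). The Id genes, which encode inhibitors of differentiation factors, stood at Id3 (0.321, 0.138 to 0.710), Id2 (1.57, 1.31 to 1.89) and Id1 (0.699, 0.592 to 0.825), and the ubiquitin ligase gene at Smurf1 (1.21, 1.01 to 1.46). Erythroid-like cells gave a median of -0.0041 (percentile 44.5), with Id2 (1.254, 0.604 to 2.85, 33 against 10 UMIs) and Bambi (1.254, 0.604 to 2.85, 33 against 10 UMIs), and HSC/MPP-like cells 0.34 (percentile 70.9), with Smurf1 (1.55, 0.975 to 2.52) and Bambi (1.52, 0.876 to 2.70). BMP ligands, receptors and SMADs had a median of 0.095 (percentile 52.4), with Twsg1 (1.27) farthest from 1. The TGF-beta pathway had 0.16 (percentile 77.8), with Ltbp1 (1.33). After thinning, 1 of 465 WT (0.00544 to 1.19%) and 6 of 658 JVF (0.335 to 1.97%) HSC/MPP-like cells had an Id2 UMI, and 2 and 0 an Id3 UMI. Among erythroid-like cells 2 of 590 WT (0.0411 to 1.22%) and 2 of 1085 JVF (0.0223 to 0.664%) had an Id2 UMI. These counts are too few to give a direction.

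The interferon response had 7 of 23 members higher and 1 lower (median 0.42, percentile 100), led by the antiviral gene Mx1 (4.72, 2.02 to 13.5, 51 against 6 UMIs). MHC class II had 5 of 7 higher (median 1.98, percentile 100), led by the invariant chain gene Cd74 (9.70, 8.06 to 11.8). Cd74 and H2 genes also lead cluster 19, which held 4 WT, 24 JVF, 0 MPN and 21 AML cells. Heme synthesis (median 0.29, percentile 99.7) was led by the enzyme gene Cpox (2.30), and erythroid transcription factors (median 0.070, percentile 68.3) by Tal1 (1.42). Early erythroid markers had a median of 0.46 (percentile 100), led by Tmem56 (3.90), and late erythroid markers 0.72 (percentile 100), led by the beta-globin gene Hbb-bt (4.41). Granulocyte progenitor markers had a median of -0.45 (percentile 0), with the granule gene Lcn2 (0.620), and megakaryocyte markers -0.065 (percentile 4.71), with Treml1 (0.604). Monocyte/dendritic progenitor markers had 0.39 (percentile 99.7), with Batf3 (27.7, 4.76 to 1118, 50 against 1 UMIs), HSC/MPP markers 0.074 (percentile 50.4), with Fgd5 (0.299), lymphoid-primed markers 0.16 (percentile 68.7), with Cd7 (3.19), and basophil/mast markers 0.064 (percentile 46.9), with Cd200r3 (5.55). Proliferation genes had medians of 0.058 (percentile 66.3) for S phase, with Rrm1 (1.41), and 0.27 (percentile 100) for G2/M phase, with Mki67 (1.43). Metabolic and stress lists had -0.14 (percentile 0.340) for glycolysis (Pkm, 0.712), 0.11 (percentile 51.2) for cholesterol synthesis (Dhcr24, 1.35) and 0.057 (percentile 57.8) for the integrated stress response (Trib3, 2.71). The remaining lists had 0.0029 (percentile 27.2) for NF-kB and inflammatory genes (Ccl3, 2.49), -0.010 (percentile 23.6) for HOXA/MEIS1 (Hoxa10, 1.51) and 0.094 (percentile 55.5) for apoptosis regulators (Bbc3, 1.499). Immediate early and heat shock genes, which respond to handling, had 0.057 (percentile 35.5), with Hspa1a (0.0430) farthest from 1.

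Among the 8 genes with the highest ratios in JVF, Igkc (876, 342 to 3216, 6314 against 4 UMIs), Igha (at least 784-fold higher, 4237 against 0 UMIs) and Iglc1 (at least 778-fold higher, 4207 against 0 UMIs) encode immunoglobulin chains and lead a shallow unnamed cluster. The stricter cell filter gave them log2 ratios of 1.61, 1.71 and 1.13. The others beyond those named above were Tcrg-C1 (379, 129 to 1838, 2048 against 3 UMIs) and Tnfsf13os (14.2). Lowest were Hspa1b (0.0907), Fbp1 (0.175), Ctsl (0.3498), Dynlt1b (0.409), Mid1 (0.453), Ppic (0.523) and Ifitm1 (0.525) and Hspa1a, which with other handling genes leads cluster 20, of 43 WT and 2 JVF cells. In erythroid-like cells Tcrg-C1 (227, 77.5 to 1101, 1791 against 3 UMIs), C2cd4a (at least 105-fold higher, 825 against 0 UMIs), Cpd (9.41) and Hbb-bt (6.22) were highest after Podxl, and Hspa1a (0.0644), Hspa1b (0.124), Ctsl (0.226), Zg16 (0.368) and Prss50 (0.375) lowest. In HSC/MPP-like cells Tnfsf13os (18.5, 9.16 to 43.5, 168 against 8 UMIs), Gdpd3 (14.4, 7.10 to 34.1, 131 against 8 UMIs), Rec8 (10.5, 5.31 to 23.5, 107 against 9 UMIs), H2-Eb1 (8.28) and Ccl3 (6.89) were highest and Hspa1b (0.0148, 0.00177 to 0.0546, 2 against 119 UMIs), Hspa1a (ratio at most 0.0254, 0 against 104 UMIs), Fbp1 (0.164), Nupr1 (0.315) and Dynlt1b (0.371) lowest.

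MPN against JVF asks what differs with Tp53 loss before leukemia, again in libraries that also differ by sex. Among the lists given here, the median ratios of JAK2/STAT5 targets, erythroid transcription factors and early erythroid markers lay above the central 95% of matched random lists, and those of interferon response and MHC class II genes and of granulocyte, monocyte/dendritic and megakaryocyte markers below it, the last above 0 under the stricter cell filter. That of p53 targets lay within it in all kept cells and below it in erythroid-like cells. Granulocyte progenitor-like cells were less frequent (ratio 0.511, 0.445 to 0.585) and HSC/MPP-like cells more frequent (1.38, 1.24 to 1.54). TMM and median-of-ratios factors move the median of all genes by -0.13 and -0.14 (log2), so list medians near 0 depend on the scaling.

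Trp53 was lower in MPN in erythroid-like cells (0.613, 0.587 to 0.639), and its ratio stayed within 1.5-fold in all kept cells (0.696, 0.675 to 0.717) and HSC/MPP-like cells (0.724, 0.641 to 0.815). Only 2 of 29 measured p53 targets were lower and 1 higher (median 0.086, percentile 9.04; -0.047 with TMM factors). Lower members were Cdkn1a (0.585, 0.502 to 0.679), at 5.49 against 9.38 CPM, and Phlda3 (0.662, 0.551 to 0.793), at 3.92 against 5.93 CPM. The growth factor gene Gdf15 (2.35, 1.202 to 4.64) was higher and Eda2r (0.656, 0.330 to 1.23) passed no limit. Medians were 0.021 (percentile 0.995) in erythroid-like cells, with Phlda3 (0.557) and Eda2r (0.526, 0.230 to 1.11, 10 against 30 UMIs), and 0.037 (percentile 11.5) in HSC/MPP-like cells, with Cdkn1a (0.458, 0.244 to 0.813) lower and the apoptosis gene Bbc3 (1.79, 1.18 to 2.74) higher. The other named genes were at Jak2 (1.31), Kit (1.19) and Ly6a (0.779) in all kept cells, Jak2 (1.40) and Kit (1.13) in erythroid-like and Jak2 (1.39), Kit (1.17) and Ly6a (0.854) in HSC/MPP-like cells.

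JAK2/STAT5 targets had 4 of 15 members higher in MPN and 0 lower (median 0.33, percentile 99.7; 0.20 with TMM factors). They were the feedback inhibitor genes Cish (1.87, 1.59 to 2.20) and Socs3 (1.796, 1.32 to 2.44), the kinase gene Pim1 (1.83, 1.76 to 1.90) and Podxl (1.82, 1.71 to 1.94). The median was 0.39 (percentile 99.98) in erythroid-like cells, led by Socs1 (2.49, 1.36 to 4.69) and Cish (1.92, 1.52 to 2.43). It was 0.32 (percentile 98.5) in HSC/MPP-like cells, with Pim1 (2.17, 2.003 to 2.35) higher and Socs2 (0.576, 0.365 to 0.887) lower.

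BMP/SMAD target genes had a median of -0.065 (percentile 3.30) over 8 members, and 0.17 with the stricter cell filter. The decoy receptor gene Bambi (0.633, 0.518 to 0.769) was lower and the SMAD corepressor gene Skil (1.57, 1.36 to 1.81) higher, though within 1.5-fold with TMM factors (log2 ratio 0.52), with Id2 (0.678) and Smad6 (0.780, 0.484 to 1.23) between the limits. Erythroid-like cells gave 0.46 (percentile 96.8), with Id1 (1.87, 0.913 to 3.90) and Skil (1.66), and HSC/MPP-like cells 0.28 (percentile 82.9), with Bambi (0.439) and Skil (1.67). BMP ligands, receptors and SMADs had 0.27 (percentile 82.2), with the signal transducer gene Smad5 (1.39), and the TGF-beta pathway 0.32 (percentile 96.5), with Tgfbi (1.57).

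The interferon response had 5 of 23 members lower in MPN (median -0.28, percentile 0), with the ubiquitin-like gene Isg15 (0.481), and MHC class II 4 of 7 (median -0.66, percentile 0), with Cd74 (0.259). Granulocyte progenitor markers had a median of -0.73 (percentile 0), with the calprotectin gene S100a9 (0.222), and monocyte/dendritic progenitor markers -0.58 (percentile 0), with Batf3 (0.115, 0.0230 to 0.357, 3 against 50 UMIs). Erythroid transcription factors had 0.41 (percentile 100), led by Sox6 (1.75), early erythroid markers 0.39 (percentile 100), led by the transferrin receptor gene Tfrc (1.67), and late erythroid markers 0.30 (percentile 91.9), led by Hemgn (1.49). Megakaryocyte markers had -0.082 (percentile 0.290), with the platelet chemokine gene Ppbp (0.218), but 0.16 with the stricter cell filter. HSC/MPP markers had 0.27 (percentile 92.2), with Fgd5 (3.20), lymphoid-primed markers -0.063 (percentile 6.08), with Igll1 (0.498, 0.183 to 1.17, 7 against 27 UMIs), and basophil/mast markers 0.29 (percentile 96.5), with Cma1 (0.351). The stricter cell filter gave Cma1 a log2 ratio of 0.099. Proliferation genes had 0.18 (percentile 84.9) for S phase, with Pcna (0.687), and 0.16 (percentile 69.2) for G2/M phase, with Plk1 (1.21). The Pcna ratio is uncertain, since Pcna shares sequence with Pcna-ps2. Pcna stood at 129 CPM in JVF and 88.8 in MPN, and Pcna-ps2 at 1.52 and 30.7. Metabolic and stress lists had 0.16 (percentile 65.4) for heme synthesis (Fech, 1.37), -0.067 (percentile 2.995) for glycolysis (Gapdh, 0.775), 0.069 (percentile 2.60) for cholesterol synthesis (Insig1, 0.788) and -0.018 (percentile 5.69) for the integrated stress response (Chac1, 0.291, 0.0887 to 0.7503, 5 against 33 UMIs, log2 ratio 0.020 after thinning). The thinned Chac1 value rests on still fewer UMIs, and no direction is drawn from it. The remaining lists had 0.17 (percentile 65.04) for NF-kB and inflammatory genes (Il1b, 0.617), 0.18 (percentile 48.2) for HOXA/MEIS1 (Hoxa10, 0.621), 0.16 (percentile 55.1) for apoptosis regulators (Bcl2l1, 1.39) and 0.068 (percentile 8.61) for immediate early and heat shock genes (Hspa1b, 0.528).

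The highest ratios in MPN were those of Pcna-ps2 (20.2) and Eif3j2 (18.4), which share sequence with Pcna and Eif3j1, so their ratios are uncertain. Next came the estrogen receptor gene Esr1 (6.24, 5.68 to 6.88) and Dnah8 (2.72), Wfdc17 (2.28), Glo1 (2.25), Sptb (2.07) and Trib2 (2.001). Lowest were the immunoglobulin genes Igha (0.000453, 1.15e-05 to 0.00253, 1 against 4237 UMIs), Igkc (0.00122, 0.000331 to 0.00312, 4 against 6314 UMIs) and Iglc1 (ratio at most 0.00137, 0 against 4207 UMIs), with Igkc and Iglc1 at log2 ratios of -0.44 and 0.050 under the stricter cell filter, and Tnfsf13os (0.0957), Gdpd3 (0.141), Hmga1 (0.166) and S100a8 (0.321). Erythroid-like cells had Esr1 (228, 104 to 622, 865 against 6 UMIs), Eif3j2 (24.6), Pcna-ps2 (21.4), Dnah8 (2.54) and Glo1 (2.11) highest and the chromatin gene Hmga1 among the lowest: Hmga1 (0.160), Elane (0.197), Mpo (0.303), Nutf2 (0.464) and Gt(ROSA)26Sor (0.469). HSC/MPP-like cells had Esr1 (2.56), Wfdc17 (2.55), Slx1b (2.47), Egr1 (2.46) and Micu1 (2.39) highest and Gdpd3 (0.0579, 0.0185 to 0.139, 5 against 131 UMIs), Hmga1 (0.140), Tnfsf13os (0.171), Hbb-bt (0.351) and Gt(ROSA)26Sor (0.379) lowest.

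AML against MPN asks what differs between leukemia and MPN on 1 genotype. Among the lists given here, the median ratios of late erythroid and monocyte/dendritic markers lay above the central 95% of matched random lists, as did those of BMP/SMAD target, MHC class II and cholesterol synthesis genes, each of which was below 0 under at least 1 alternative. Those of TGF-beta pathway genes, erythroid transcription factors, megakaryocyte and basophil/mast markers and handling genes lay below it. The random lists were not matched on transcript length, and the median log2 ratio of genes fell from 0.077 in the shortest of 10 length bins to -0.31 in the longest, a trend these percentiles do not remove. Monocyte/dendritic progenitor-like cells were more frequent (ratio 1.83, 1.57 to 2.13), and megakaryocyte-like cells less frequent (0.571, 0.481 to 0.678). Lymphoid-primed cells had a ratio of 4.37 (2.89 to 6.83), but the direction turned with 15 components (-5.17 percentage points). TMM and median-of-ratios factors move the median of all genes by 0.10 and 0.12.

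BMP/SMAD target genes had 3 members higher and 2 lower of 8 in AML (median 0.24, percentile 98.4). Higher were Id2 (2.04, 1.70 to 2.45), at 7.99 against 3.92 CPM, Id1 (1.86, 1.54 to 2.26), at 6.81 against 3.66 CPM, and the inhibitory SMAD gene Smad6 (1.74, 1.10 to 2.82), and the ubiquitin ligase gene Smurf1 (0.585, 0.478 to 0.716) was lower. The median depends on which thinly counted members are let in and on the mix of cells: with members of at least 1 UMI in each library it was -0.092, and with equal class weights 0.047. Id1 had a log2 ratio of 0.90, but 0.21 without the AML-only cluster (an alternative chosen after seeing the data) and -0.057 with equal class weights. Equal class weights also leave out that cluster, here and for the list median, so these settings are not separate checks. After thinning, 5.07% of the AML-only cluster (17 of 335, 2.98 to 8.001%) and 0 of 832 AML erythroid-like cells had an Id1 UMI, with median depths of 20269 and 22039 UMIs before thinning. The ligand gene Bmp4 (221, 75.4 to 1074, 883 against 3 UMIs) leads the AML-only cluster, which held 762 of those UMIs, and BMP ligands, receptors and SMADs had a median of -0.27 (percentile 28.4). BMP/SMAD target medians were -0.40 (percentile 20.3) in erythroid-like cells, with Smurf1 (0.463) and Smurf2 (0.708), and -0.33 (percentile 33.1) in HSC/MPP-like cells, with Smurf1 (0.411) and Id2 (2.21, 0.987 to 5.28, 20 against 10 UMIs). The TGF-beta pathway had 6 of 11 members lower (median -0.64, percentile 0.0850), with the signal transducer gene Smad3 (0.386).

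The p53 targets had 7 of 28 members lower in AML and 0 higher (median -0.31, percentile 6.50). They included Zmat3 (0.380, 0.305 to 0.471), at 2.35 against 6.19 CPM, Gdf15 (0.444, 0.205 to 0.920), the death receptor gene Tnfrsf10b (0.481, 0.317 to 0.723) and Cdkn1a (0.484, 0.391 to 0.598), at 2.66 against 5.49 CPM. Thinning, which also leaves fewer UMIs of these genes, gave log2 ratios of -0.10 for Gdf15 and -0.27 for Tnfrsf10b, against -1.17 and -1.06. The stricter cell filter gave Cdkn1a -0.40, against -1.05. All of these lay within 1.5-fold. In erythroid-like cells the median was -0.38 (percentile 1.90), with Cdkn1a (0.161) and Phlda3 (0.336), and in HSC/MPP-like cells -0.13 (percentile 75.2), with Ccng1 (0.591) and Btg2 (0.676). For Phlda3 in erythroid-like cells the stricter cell filter gave a log2 ratio of -0.040, against -1.57. After thinning, 1 of 590 WT (0.00429 to 0.941%), 11 of 1085 JVF (0.507 to 1.81%), 9 of 954 MPN (0.432 to 1.78%) and 2 of 832 AML (0.0291 to 0.866%) erythroid-like cells had a Cdkn1a UMI, and 30.3%, 39.2%, 25.4% and 24.2% a Trp53 UMI. Trp53 stood at 0.837 (0.807 to 0.867) in all kept cells, 0.968 (0.919 to 1.02) in erythroid-like cells and 1.07 (0.933 to 1.24) in HSC/MPP-like cells. The AML-only cluster held 47.8 CPM of Trp53, against 147 in AML erythroid-like cells.

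JAK2/STAT5 targets had 4 of 15 members lower in AML and 2 higher (median -0.26, percentile 10.7). Lower were Podxl (0.392, 0.363 to 0.424), at 18.2 against 46.5 CPM, the survival gene Bcl2l1 (0.553, 0.468 to 0.653) and the cyclin gene Ccnd2 (0.582, 0.566 to 0.598), and Socs1 (1.63, 1.27 to 2.12) was higher. Over all deposited barcodes, also an alternative chosen after seeing the data, the median was 0.00034. Podxl had a log2 ratio of -0.27 there, against -1.35 in all kept cells. Erythroid-like cells had -0.44 (percentile 0.745), with Podxl (0.384) and Pim2 (0.483), and HSC/MPP-like cells -0.065 (percentile 76.7), with Cdk6 (0.619) and Bcl2l1 (0.623, 0.352 to 1.08). Jak2 itself was at 0.627 (0.576 to 0.683) in all kept cells, 0.685 (0.602 to 0.780) in erythroid-like cells and 0.656 (0.469 to 0.912) in HSC/MPP-like cells. In all kept cells its log2 ratio was -0.67, but it stayed within 1.5-fold with TMM (-0.57) and median-of-ratios factors (-0.55), thinning (-0.32), equal class weights (-0.45) and all deposited barcodes (-0.42), so no call is drawn from it. The remaining named genes were at Kit (1.248) and Ly6a (0.922, 0.808 to 1.05) in all kept cells, Kit (1.482) in erythroid-like and Kit (1.30) and Ly6a (1.05, 0.896 to 1.23) in HSC/MPP-like cells.

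Late erythroid markers had 8 of 14 members higher in AML (median 1.04, percentile 100, 0.55 without the AML-only cluster), led by the globin genes Hbb-bt (9.12), Hba-a1 (6.98) and Hbb-bs (3.55). Their log2 ratios of 3.19, 2.80 and 1.83 fell to 1.19, 0.98 and 0.88 without that cluster. Monocyte/dendritic progenitor markers had 8 of 11 higher (median 1.03, percentile 100), led by the chemokine receptor gene Xcr1 (10.5, 2.65 to 91.0, 28 against 2 UMIs). MHC class II had 0.83 (percentile 100), led by Cd74 (6.76), but the list and Cd74 were both at -0.12 with the stricter cell filter. Erythroid transcription factors had -0.45 (percentile 0.0450), with Gata2 (0.467), megakaryocyte markers -0.58 (percentile 0.130), with the integrin gene Itga2b (0.359), and basophil/mast markers -0.57 (percentile 0.25), with the protease gene Prss34 (0.189). Immediate early and heat shock genes had -0.69 (percentile 0), with Fosb (0.1001). Heme synthesis had 0.071 (percentile 90.6), led by the enzyme gene Alas2 (6.17, 3.08 to 14.0, 74 against 9 UMIs), which the stricter cell filter put at a log2 ratio of -0.018. Early erythroid markers had -0.11 (percentile 26.1), with Aqp1 (0.437), HSC/MPP markers -0.39 (percentile 3.51), with Esam (0.414), lymphoid-primed markers 0.30 (percentile 94.995), with Ccr9 (6.94, 2.49 to 26.8, 37 against 4 UMIs), and granulocyte progenitor markers 0.20 (percentile 96.0), with Fcnb (2.44). Proliferation genes had -0.16 (percentile 11.1) for S phase, with the replication gene Mcm2 (0.570), and -0.0096 (percentile 74.95) for G2/M phase, with Nusap1 (1.44). Interferon response had -0.30 (percentile 9.28), with Stat1 (0.526). Metabolic and stress lists had 0.030 (percentile 75.6) for glycolysis (Slc2a3, 0.551), 0.050 (percentile 97.6) for cholesterol synthesis (Dhcr24 (0.378); median -0.094 with the stricter cell filter and -0.019 without the AML-only cluster) and -0.14 (percentile 31.4) for the integrated stress response (Vldlr, 0.479). The remaining lists had -0.19 (percentile 34.0) for NF-kB and inflammatory genes (Nfkb2, 0.552), -0.29 (percentile 19.3) for HOXA/MEIS1 (Meis1, 0.589) and -0.18 (percentile 33.4) for apoptosis regulators (Bak1, 0.534).

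The highest ratio in AML was that of the tumor suppressor gene Cdkn2a (522, 178 to 2533, 2086 against 3 UMIs), and 1852 of its UMIs lay in the AML-only cluster, which it leads together with Gml2 (32.2). Beyond these and the globin genes, Slc24a5 (4.44) and Rpgrip1 (3.51) were highest. Lowest were the nucleoside diphosphate kinase gene Nme2 (0.0302, 0.0276 to 0.0331), the eosinophil granule gene Prg2 (0.106) and Phpt1 (0.141), Dynlt1b (0.174), Bloc1s1 (0.184), Grcc10 (0.215) and Lars2 (0.230). Nme2, Phpt1, Bloc1s1 and Grcc10 have exons that overlap another gene, so their ratios are uncertain. Erythroid-like cells had Slc24a5 (4.90), Rpgrip1 (4.04), Rbm4b (3.33), Gsdme (2.63) and Rpa3 (2.52) highest and Nme2 (0.0247), Phpt1 (0.115), Dynlt1b (0.137), Bloc1s1 (0.192) and Lars2 (0.224) lowest. HSC/MPP-like cells had Ces2g (3.84), Npl (3.27), Gsdme (3.24), Tmem128 (3.02) and Rbm4b (2.98) highest and Nme2 (0.0294), Phpt1 (0.161), Hist1h2ap (0.183), Bloc1s1 (0.193) and Grcc10 (0.214) lowest.

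AML against WT spans the series. JAK2/STAT5 targets had 7 of 15 members higher and 0 lower (median 0.57, percentile 99.98). The p53 targets had a median of 0.093 (percentile 49.9) and BMP/SMAD target genes 0.080 (percentile 54.7). Named genes stood at Trp53 (1.01, 0.974 to 1.05), Jak2 (1.196), Kit (1.39) and Ly6a (0.887, 0.781 to 1.01) in all kept cells, Trp53 (0.897), Jak2 (1.09, 0.919 to 1.29) and Kit (1.18) in erythroid-like and Trp53 (1.47), Jak2 (1.58), Kit (1.94) and Ly6a (1.497) in HSC/MPP-like cells.

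**Figure D2:**
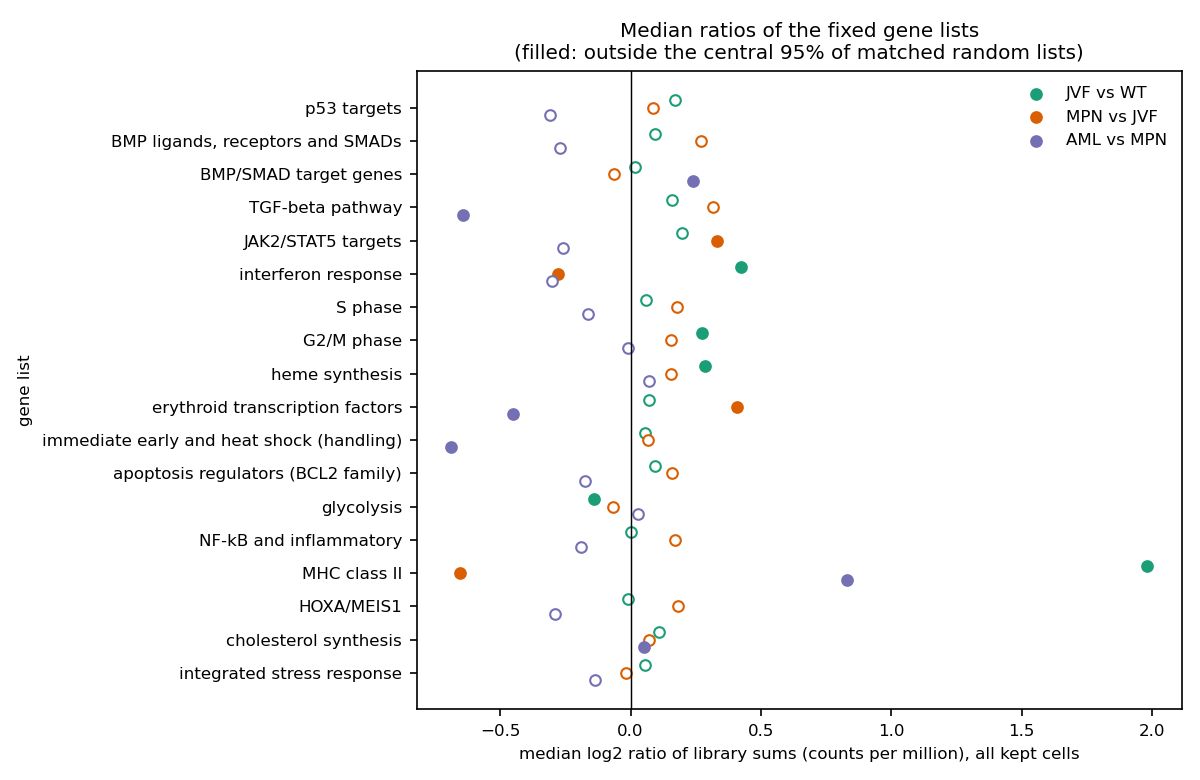
Median log2 ratio of library sums (x axis) of each of the 18 fixed gene lists (y axis), with 1 point per comparison, filled where it lies outside the central 95% of matched random lists. MHC class II was at 1.98 in JVF against WT, -0.66 in MPN against JVF and 0.83 in AML against MPN, the last not kept under the stricter cell filter.

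**Figure D3:**
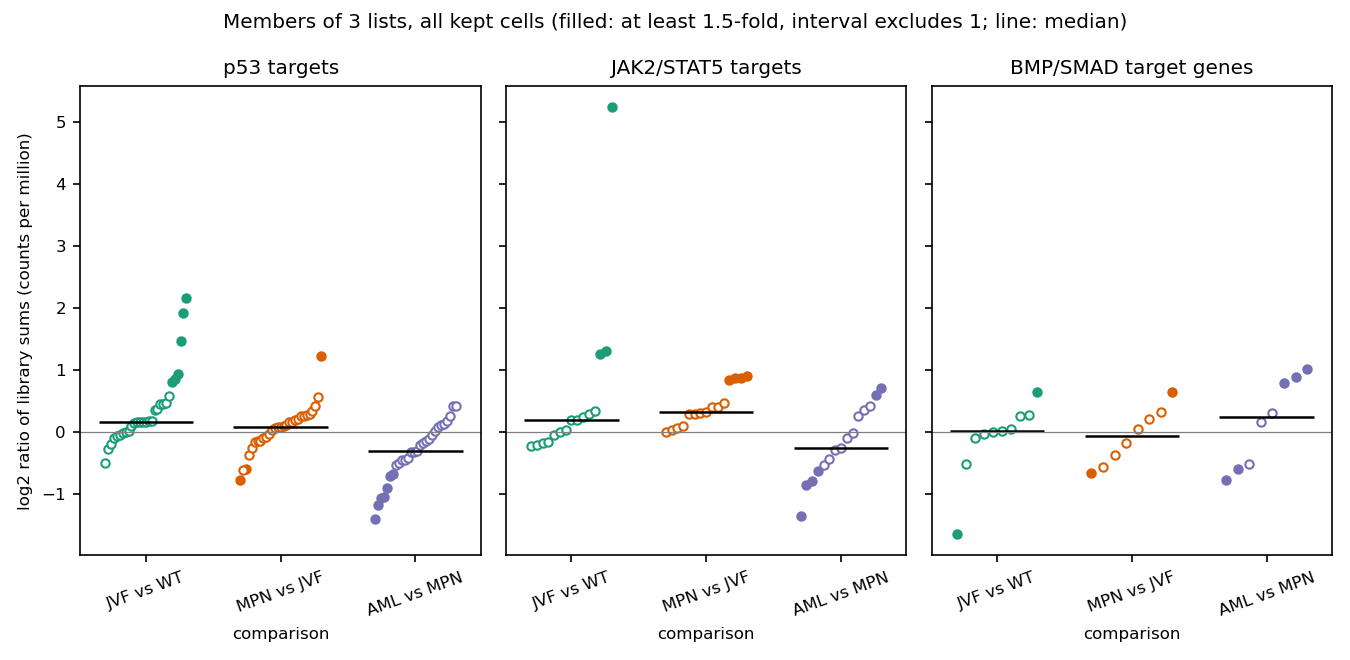
Log2 ratio of library sums (y axis) of each measured member (1 point per gene) of 3 lists in 3 comparisons (x axis), filled where the ratio is at least 1.5-fold with an interval that leaves out 1, with medians as lines. The p53 targets had medians of 0.17, 0.086 and -0.31, the middle one -0.047 with TMM factors.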

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

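The tests of free RNA and of a few strongly expressed genes were chosen only after the result was seen. Barcodes with 40 to 65% mitochondrial UMIs, which the cell filter removes and only the alternative of all deposited barcodes uses, carried the leading genes of the AML-only cluster. In 4779 such AML barcodes (42.5% of the library), the 8 leading genes other than hemoglobins made up 1081 UMIs in every 1e+06 non-mitochondrial UMIs. The same measure was 65.5 in WT, 122 in JVF and 88.0 in MPN barcodes of that range, and 2738 in the AML-only cluster.

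Against AML erythroid-like cells, the AML-only cluster had chromosome medians, relative to all genes, of -0.80 for chromosome 6, -0.66 for chromosome 10, 0.60 for chromosome 15 and -0.37 for chromosome 19 (log2). AML against MPN erythroid-like cells had 0.014, 0.043, -0.038 and -0.0019 in that order.

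Free RNA with the make-up of all AML barcodes would keep Mpo in proportion to these genes. Mpo UMIs per UMI of the 8 genes were 0.0715 in the high-mitochondrial AML barcodes and 2.25 in all AML barcodes, a ratio of 0.0318. That argues against this form only. The AML-only cluster itself had 0.00285, so free RNA shed mainly by that population would be low in Mpo too. The test cannot decide on such RNA, which stays open. By the measure given above, the 8 genes stood at 173 in kept AML cells outside that cluster. Kept cells of WT, JVF and MPN had 58.5, 101 and 117. Each of the 8 genes was higher in kept AML cells outside that cluster than in kept MPN cells, by unlike amounts. Bex4 stood at 86.1 against 61.1 and Cela1 at 45.1 against 37.3. Cdkn2a stood at 5.09 against 0.0762 and Bmp4 at 2.63 against 0.0762. A few strongly expressed genes are argued against for chromosome 6 in the AML-only cluster, where a share of 0.903 of its genes lay below the median of all genes. For chromosomes 10 and 19 there the test cannot tell. Most of their genes (300 of 429 and 222 of 317) lay below that median, but fewer than the limit set for arguing against. The lower of the 2 shares was 0.699, on chromosome 10, and the lower interval limits were 65.3% and 64.7%. Nor can the test tell for chromosome 6 in the high-mitochondrial AML barcodes against MPN barcodes of that range. There 277 of 349 genes lay below, a share of 0.794, with an interval of 74.7 to 83.5% that reached under the limit set. Damaged cells of the population seen as the AML-only cluster stay open: against MPN barcodes of the same range the high-mitochondrial AML barcodes had a chromosome 6 median of -0.53, with -0.32 for chromosome 10 and 0.41 for chromosome 15. WT and JVF barcodes of that range against MPN had chromosome 6 medians of 0.011 and -0.019. A hypothesis is that these barcodes may hold damaged cells of a clone with chromosome losses and gains, which DNA data would have to test.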

How the results depend on the processing

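The alternatives "all deposited barcodes" and "without the AML-only cluster" were chosen only after the results were seen. So was the limit on which lists and list members the text reports, which was written after the outcomes of the alternatives had been seen. Over everything computed, 10199 of 12714 alternative gene ratios stayed within their interval, 2432 moved and 83 reversed. For medians these were 2315, 600 and 46 of 2961, and for shares 145, 82 and 27 of 254. Over what the text reports they were 2183, 556 and 8 of 2747 gene ratios, 809, 214 and 8 of 1031 medians and 117, 55 and 20 of 192 shares. All 40 alternative chromosome medians of the AML-only cluster stayed. The cause was not tested for any of the following.

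Of 216 reported calls of higher or lower, 47 were no longer 1.5-fold in their direction under at least 1 alternative, 7 of them with TMM factors, 9 with median-of-ratios factors, 24 with the stricter cell filter and 19 after thinning. In JVF against WT they were Ppic, Eda2r, Pvt1, Id2, Socs2, Hoxa10, Lcn2 and Treml1 in all kept cells; Trp53 in erythroid-like cells; Jak2, Ly6a, Btg2 and Socs2 in HSC/MPP-like cells. In MPN against JVF they were Igkc, Iglc1, Phlda3, Bambi, Skil, Tgfbi, Podxl, Socs3, Il1b, Chac1, Tfrc and Cma1 in all kept cells; Skil in erythroid-like cells; Bbc3 and Socs2 in HSC/MPP-like cells. In AML against MPN they were Cd74, Jak2, Gdf15, Tnfrsf10b, Cdkn1a, Id1, Smad6, Smurf1, Podxl, Socs1, Alas2, Gata2, Meis1 and Fcnb in all kept cells; Phlda3 and Pim2 in erythroid-like cells; Jak2 and Cdk6 in HSC/MPP-like cells. In AML against WT it was Jak2 in HSC/MPP-like cells. This count was chosen only after the results were seen.

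TMM and median-of-ratios factors gave p53 target medians of 0.11 and 0.094 in JVF against WT, and in MPN against JVF -0.047 and -0.053 (erythroid-like -0.11 and -0.12). In that comparison BMP/SMAD targets had -0.20 and -0.20, and JAK2/STAT5 targets 0.20 and 0.19. Equal class weights gave 0.23 for BMP/SMAD and 0.25 for JAK2/STAT5 targets in JVF against WT, and in AML against MPN 0.047 for BMP/SMAD targets and -0.057 for Id1. In the AML library these weights also leave out the AML-only cluster. At least 1 UMI in each library gave BMP/SMAD targets -0.092 in AML against MPN. All deposited barcodes gave JAK2/STAT5 targets 0.00034, and leaving out the AML-only cluster gave cholesterol synthesis -0.019. Keeping doublets gave p53 targets -0.017 in MPN against JVF erythroid-like cells.

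The stricter cell filter passed 2778 WT, 3790 JVF, 1727 MPN and 1639 AML barcodes, and doublet removal changed with it. The fallback rate took 7.78% of WT, 6.95% of MPN and 9.03% of AML cells, and the automatic threshold 1.95% of JVF cells. Values under this filter thus also differ in doublet removal. With the looser filter the fallback applied to AML only. The stricter filter gave, in MPN against JVF, 0.17 for BMP/SMAD targets, 0.16 for megakaryocyte markers, 0.050 for Iglc1 and 0.099 for Cma1. In AML against MPN it gave -0.12 for MHC class II, -0.12 for Cd74, -0.094 for cholesterol synthesis and -0.018 for Alas2, and -0.16 for Socs2 in JVF against WT HSC/MPP-like cells. Thinning gave -1.32 for Eda2r in JVF against WT and 0.020 for Chac1 in MPN against JVF. Both rest on the few UMIs left by thinning, with any library at 0 set to 3 counts, so neither gives a direction.

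Class shares moved most, here as differences in percentage points. In JVF against WT the looser filter gave 2.79 for HSC/MPP-like, 8.09 for erythroid-like and -17.2 for unnamed cells, and the stricter filter -5.82 for erythroid-like cells. Resolution 0.5 gave -0.0125 for erythroid-like cells, and resolution 2.0 0.417 for HSC/MPP-like, 11.2 for erythroid-like and -0.395 for unnamed cells. With 15 components, erythroid-like, lymphoid-primed and unnamed cells were at 4.90, 2.73 and -3.45, and with each library alone at 10.4, 5.69 and -14.3. Without cell cycle genes, erythroid-like and unnamed cells were at 5.90 and -1.76.

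In MPN against JVF erythroid-like cells were at 6.52 at resolution 0.5 and -19.8 with each library alone, monocyte/dendritic cells at 0.0836 with the stricter filter and 3.11 alone, and lymphoid-primed cells at 3.20 with 15 components. In AML against MPN the share of AML-only clusters among AML cells was 13.4% with the looser filter and 20.96% at resolution 2.0, and had no value with the stricter filter, under which no such cluster formed. That filter's mitochondrial limit of 5% lies below the median of 7.11% in the 336-cell cluster. Erythroid-like cells were at -2.77 (looser), -1.90 (stricter), -8.45 (resolution 0.5), -2.73 (15 components), -8.92 (no cell cycle genes) and 22.4 (each alone). With 15 components HSC/MPP-like cells were at 0.834 and lymphoid-primed cells at -5.17, with granulocyte progenitor-like cells at -0.234 at resolution 2.0 and unnamed cells at 0.135 at resolution 0.5.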

Other observations

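The tests of a linked segment and of a recombinase were chosen only after the results were seen, and the genes named here were singled out after their values were seen. Apart from these, no biological explanation was tested. A set of 34 genes was lower in AML than in MPN in each of the 5 cell classes compared, among them Nme2 (499.9, 450.4, 293 and 8.85 CPM in WT, JVF, MPN and AML) and Uba52 (4758, 4378, 3648 and 944). Short transcripts are argued against only for the set as a whole: its median longest transcript was at percentile 96.5 of random sets matched on expression. The set mixes lengths, so this median does not decide for each member. Nme2 and Uba52 had longest transcripts of 1012 and 711 nt, and Lars2 one of 3894 nt. Short length stays open for members such as the first of these. A trend with length in the other direction is not excluded, since the median log2 ratio over all genes was 0.077 in the shortest of 10 length bins and -0.31 in the longest. Reads shared with overlapping genes stay open: 29.4% of the set had an exon overlapping another gene on the same strand, against a median of 5.88% in random sets (percentile 100), so a different read assignment in the AML library may explain part of the set.

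A set of 4 genes differed the same way in each of these classes between both Tp53 null libraries and the others: Esr1, Eif3j2 and Pcna-ps2 were higher and Hmga1 lower. These genes lie on chromosomes 10 (Esr1), 18 (Eif3j2), 19 (Pcna-ps2) and 17 (Hmga1). That argues against a single linked segment of another strain for the whole set. A segment that holds only part of the set stays open. No pair lay within 5 Mb, but random sets had a median of 0 such pairs too (percentile 48.3), so the test of nearby pairs decides nothing. On chromosome 17, Glo1 (start 30584936; 99.7, 111, 250.4 and 350.3 CPM in WT, JVF, MPN and AML) and Dnah8 (start 30624354; 22.9, 20.9, 56.9 and 67.7) lie near Hmga1 (start 27556497). Esr1 was at 6.64 CPM in WT, 7.003 in JVF, 43.7 in MPN and 47.1 in AML. A recombinase fused to an estrogen receptor and present in every cell may explain it: the highest class exceeded the lowest by a factor of 1.30 in MPN and 1.21 in AML. In WT and JVF the highest class, HSC/MPP-like, was at 12.4 and 19.9 CPM, and the lowest, erythroid-like, held 3 and 6 UMIs (0.257 CPM, 0.0530 to 0.7505, and 0.195 CPM, 0.0716 to 0.425). The labels name no recombinase, so this remains a hypothesis.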
